A study of Mus musculus with 12 samples.

How the data were processed

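MicroRNAs (miRNAs) were measured in total RNA from mouse distal colon tissue with 12 single-colour Agilent miRNA arrays (Cy3, array design 031184), 3 each for untreated mice (Control), the carcinogen azoxymethane (AOM), the colitis-inducing polymer dextran sulfate sodium (DSS), and both (AOM/DSS). Per the labels' protocols, RNA was extracted with a mirVana kit, its integrity was checked on a Bioanalyzer, and it was labelled with Agilent's miRNA kit. Per the labels' protocols, epithelium of the Control, AOM and DSS mice was scraped with a slide into Trizol, whereas neoplasms of the AOM/DSS mice were clipped with scissors into RNA storage solution, so the way of collecting tissue cannot be separated from the AOM/DSS group.

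Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, and the deposited scanner values are spot intensities: a background-subtracted processed signal, median spot and local background intensities, a total gene signal per miRNA, and flags per spot. No normalization between arrays was found in these intensity columns. The deposited value table is on a log2 scale with undetected miRNAs at a low value of each array. Neither the headers nor the labels used here state its normalization or centring. Its column medians were -3.23, -3.09 and -3.31 for Control, -3.17, -3.26 and -3.30 for AOM, -3.21, -3.21 and -3.26 for DSS, and -3.29, -3.25 and -3.32 for AOM/DSS. Each equals that low value, so these medians say nothing about centring. Over detected miRNAs the medians were 5.33, 5.86 and 4.44 for Control and 5.60, 5.08 and 4.72 for AOM. They were 5.41, 5.44 and 5.16 for DSS and 4.83, 5.24 and 4.15 for AOM/DSS. The deposited table served only as an alternative, matched by 1078 of the 1080 names on the array.

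The processed signal of each spot was used without control spots and without spots that the scanner software marked as outliers. Spots of the same probe were averaged. Each array was divided by the 75th percentile of its signal over the 200 probes well above background on all 12 arrays. A probe counted as well above background when most of its spots carried that flag. Values under a common floor of 0.0381 (-4.71 on the log2 scale; the median over arrays of the lowest detected scaled signal) were set to it before taking log2. Each of the 1080 miRNA names, covered by 2780 probes, was represented by its brightest probe over all arrays. The 171 names whose probe was well above background on all 3 arrays of at least 1 group were tested, of which 114 were so on all 12 arrays. A miRNA well above background on no array of a group was compared with this same floor, as a lower bound ("at least"), where the other group was above the floor on all its arrays.

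Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, in a model of 4 group means over all 12 arrays with 8 residual degrees of freedom and 3.42 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05; all adjusted p-values come from limma. Tables were read with data.table (1.17.8) and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All 6 contrasts of group pairs were tested, and a departure from additivity: the AOM/DSS minus DSS difference less the AOM minus Control difference. Because the AOM dose and number of injections differ between the AOM and AOM/DSS groups, the last contrast is not a clean factorial term.

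Fixed lists of miRNAs (miR-17~miR-92a and its paralogous clusters, the miR-200, let-7, miR-29, miR-30 and miR-15/16 families, intestinal epithelium-enriched, commonly reported higher or lower in colorectal tumours, inflammation-induced, p53-responsive, the Dlk1-Dio3 cluster) and marker lists (epithelium, smooth and striated muscle, fibroblast and other mesenchymal cells, leukocytes, erythrocytes, endothelium, neurons and enteroendocrine cells) were tested with limma's camera against the other tested miRNAs. The preset correlation between miRNAs was 0.01, lists with at least 3 tested members were used, and p-values were adjusted over the 15 such lists within a comparison. The lists overlap: the epithelium list holds the miR-200 family and members of the intestinal and p53 lists, the muscle members are also on the list commonly reported lower in tumours, and miR-223 is on the leukocyte, inflammation and tumour-higher lists. Old array names were matched to current arm names (miR-21 for miR-21-5p, an asterisk for the minor arm). miR-106a, miR-424, miR-199b-5p and miR-486 were not found under these names, and miR-34c-3p was left out. Near-identical relatives, such as miR-20a and miR-20b or the let-7 members, may share signal on 1 probe, so differences between relatives are uncertain.

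The lists, the comparisons and the rule for the miRNAs to name were fixed before the data were examined. Named were the 10 largest rises and falls against Control, and the 5 largest in the other comparisons, among miRNAs past the threshold whose arrays did not overlap between groups. From each list up to 4 members with the smallest p in AOM/DSS against Control were added, as were 13 miRNAs always named: miR-21, miR-31, miR-135b, miR-143, miR-145, miR-133a, miR-215, miR-192, miR-146a, miR-155, miR-223, miR-142-3p and miR-34a. Where none passed, the 3 with the smallest p were named.

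Alternatives were background correction by normexp (offset 50), other scalings, quantile normalization, the total gene signal, the mean of all probes, the deposited table, other filters and a lower floor, a trended robust prior, fits of only the groups compared, replicate number or slide as a block, array weights, and leaving out each array. Lists were also tested with an estimated correlation, with camera on ranks and with fry. The mean spot intensity planned for normexp was absent from the files, so the median spot intensity took its place. From the headers, replicates 1 and 2 of every group shared slide 1, and replicate 3 of every group slide 2, scanned on another day. The correlation within slides was -0.0391.

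The arrays held 43200 spots each, of which 4588 to 7504 were well above background and none was saturated. Precision is limited by the 3 arrays per group. The labels do not state that replicates are separate animals, so p-values measure the spread between the samples as deposited. The procedure was tested on simulated data for AOM/DSS against Control, with 40 of 171 miRNAs changed in 20 simulations. A log2 change of 1 was found in 63.8% of changed miRNAs and a change of 2 in 93.0%. Of the calls, 1.93% and 5.98% fell on unchanged miRNAs. For DSS against Control the shares found were 66.1% and 93.6%. The simulated values had independent noise for each miRNA around the Control means, without a floor, correlated miRNAs or outlying arrays. They therefore do not show how the procedure fares with such features of these data. Genome positions were used only to find which miRNA genes neighbour each other (GRCm38.p6), because the headers name another build, mm9.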

Results

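miRNA levels were measured in distal colon tissue of female BALB/c mice, 5 to 7 weeks old at the start, collected at day 100, when tumours had formed in the AOM/DSS mice. Each of the 4 groups had 3 arrays. Control mice were untreated. The AOM group received 10 mg/kg of azoxymethane, a colon carcinogen, in 6 weekly injections. The DSS group drank dextran sulfate sodium, which injures the colon epithelium, for 5 days in each of 3 cycles of 21 days from day 5. The AOM/DSS group received 12.5 mg/kg AOM in 1 injection and the same DSS cycles, and its samples were clipped neoplasms, whereas scraped epithelium was taken from the other groups. Of 2780 probes, 262, 223 and 333 were well above background on the Control arrays, 256, 293 and 335 on the AOM arrays, 249, 259 and 276 on the DSS arrays, and 337, 291 and 389 on the AOM/DSS arrays. Values below are log2 of scaled signal, given as mean ± SD over 3 arrays, and 171 miRNAs were tested.

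The neoplasms stood apart from the other tissues on the first principal component. The first principal component held 52.5% of the variance, with the AOM/DSS arrays at 8.16 to 9.13, AOM arrays 1, 2 and 3 at -2.86, 2.17 and 2.55, the DSS arrays at -4.08 to -3.48 and the Control arrays at -6.38 to -4.57. The second component held 18.9% and set Control array 2 (-7.90) and AOM array 1 (6.52) apart from the rest. By Pearson's r, AOM/DSS array 1 was as close to AOM arrays 2 and 3 (0.961 and 0.965) as to AOM/DSS arrays 2 and 3 (0.955 and 0.962). AOM/DSS arrays 2 and 3 were closer to their own group than to any other array.

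**Figure D1:**
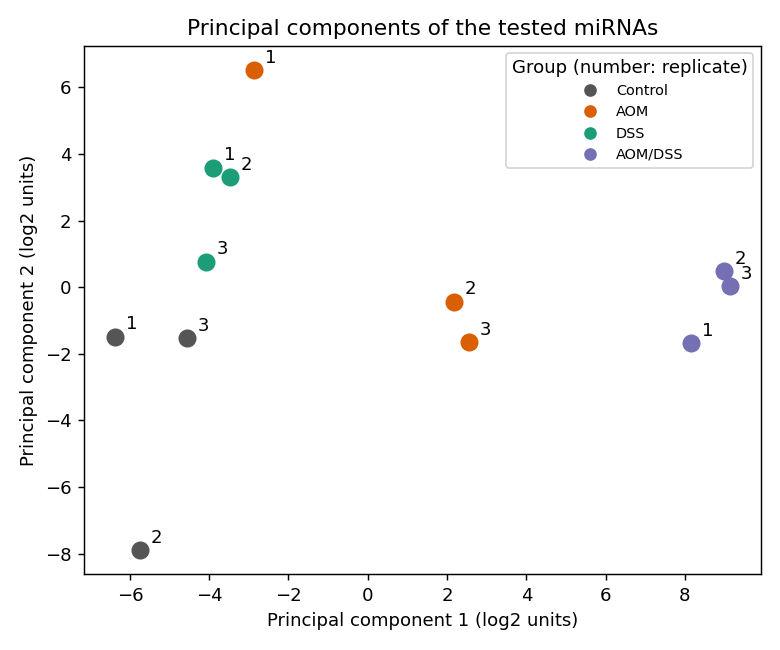
First and second principal components (log2 units) of the 171 tested miRNAs, with 1 point per array, coloured by group and numbered by replicate. The AOM/DSS arrays lie at 8.16 or more on the first component, and AOM array 1 lies apart from AOM arrays 2 and 3.

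AOM/DSS against Control addresses which miRNAs differ between colitis-associated tumours and untreated colon epithelium. miR-31, an epithelial miRNA often reported high in colorectal tumours, was well above background on all AOM/DSS arrays (0.01 ± 0.32, n = 3) and on no Control array, a rise of at least 26.4-fold (adjusted p = 0.000218), and its minor arm miR-31* rose at least 9.78-fold. miR-34a, a transcriptional target of p53, rose 10.4-fold, from -3.58 ± 0.45 to -0.20 ± 0.26 (n = 3 each; log2 difference 3.38, SE 0.32, adjusted p = 3.05e-05). miR-215, abundant in differentiated gut epithelium, was 26.3-fold lower, from 1.14 ± 0.45 to -3.58 ± 0.91 (log2 difference -4.72, SE 0.41, adjusted p = 2.17e-05). In all, 63 miRNAs passed the limma threshold, 49 higher and 14 lower in the neoplasms.

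Other large rises were those of miR-205, a miRNA of stratified epithelia (log2 difference 2.91, or 3.79 with the floor lowered 4 times; well above background on 1 of 3 Control arrays), miR-146b (4.20-fold), miR-211* (4.15-fold), the myeloid miR-223 (4.13-fold, adjusted p = 0.000275), miR-1897-5p (at least 3.74-fold), miR-497 (3.52-fold) and miR-483, encoded within the Igf2 gene (at least 3.50-fold). Other large falls were those of miR-378 (5.19-fold lower), miR-375, which is enriched in enteroendocrine cells (4.47-fold lower, adjusted p = 0.00012), miR-139-5p (at least 3.72-fold lower), miR-494 (3.46-fold lower), miR-194 (2.73-fold lower) and miR-192 (2.02-fold lower), with miR-192*, miR-365 and miR-193 at log2 differences of -1.09, -0.87 and -0.81. miR-192* and miR-193 were well above background on 1 and 2 of the 3 AOM/DSS arrays. miR-135b, which targets Apc, rose at least 2.21-fold (adjusted p = 0.000958), and miR-21, the brightest of the named miRNAs, rose 2.16-fold from 4.38 ± 0.16 to 5.49 ± 0.13 (adjusted p = 0.00202). miR-21 ranked first on every array, so quantile normalization left it no difference, and median scaling ended its call (adjusted p = 0.054). Normexp ended the calls of miR-192* (0.136), miR-193 (0.136) and miR-365 (0.205), and the percentile over all probes those of miR-193 (0.145) and miR-365 (0.0744). miR-193 missed the threshold without any 1 of Control array 1 (adjusted p = 0.0651), Control array 3 (0.0821) or AOM/DSS array 1 (0.0506), 2 (0.0757) or 3 (0.0697), and with the mean of all probes (0.0537). Without a filter on dim probes the calls of miR-146b (0.0959), miR-211* (0.0726), miR-497 (0.154), miR-483 (0.12), miR-494 (0.179), miR-192, miR-365 (both 0.0911) and miR-193 (0.263) ended, and within slide 1 those of miR-146b (0.0548), miR-365 (0.0942) and miR-193 (0.169).

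**Figure D2:**
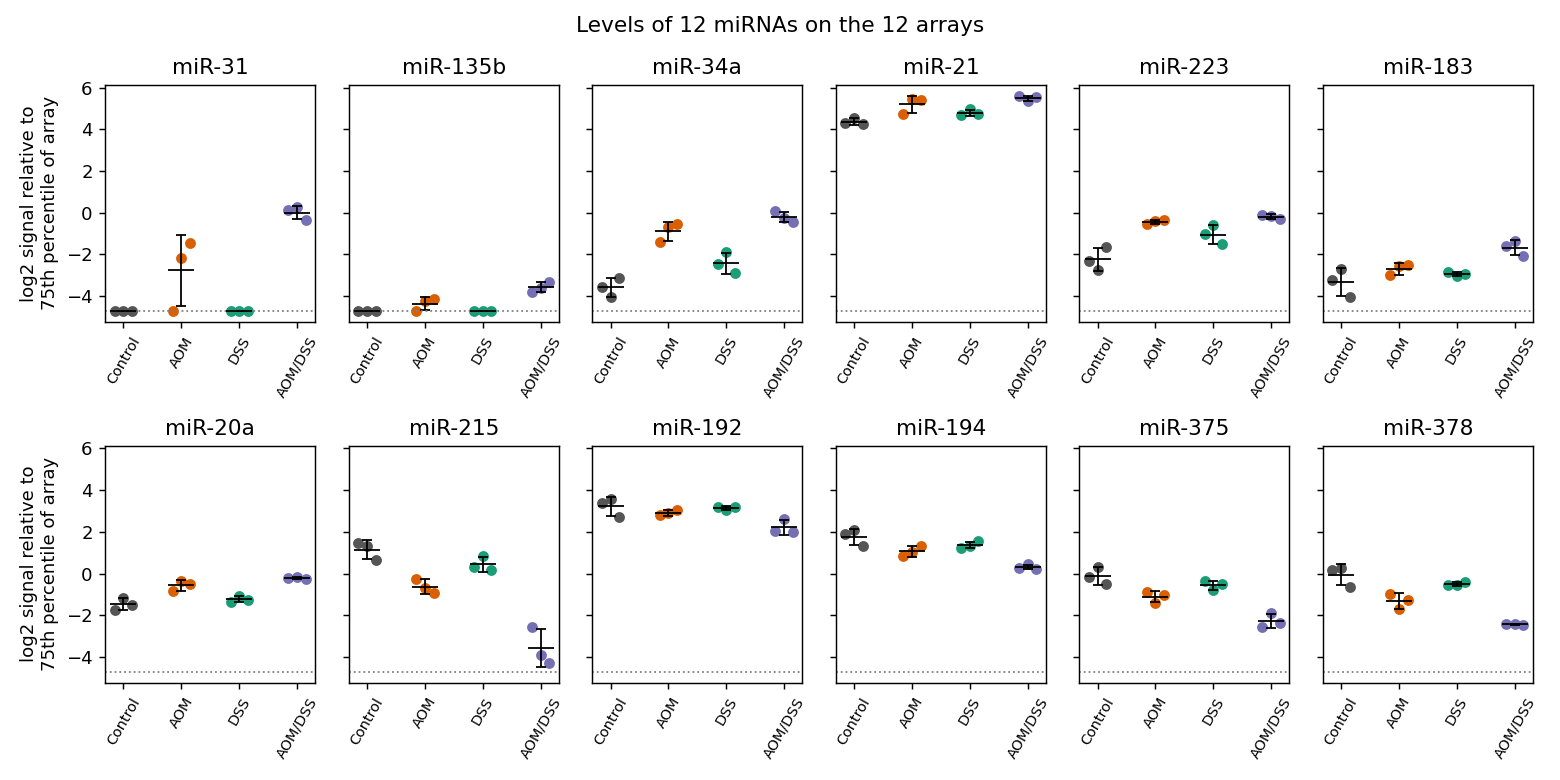
Log2 scaled signal of 12 miRNAs in the 4 groups, with 1 point per array, bars for the mean ± SD (n = 3) and a dotted line at the floor of -4.71. miR-215 falls from 1.14 in Control to -3.58 in AOM/DSS, and miR-34a goes from -3.58 to -0.20.

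Proliferation-linked miRNAs rose together: 8 of the 9 measured members of the miR-17~miR-92a cluster and its paralogues rose and none fell, including miR-20b (log2 difference 1.20), miR-20a (1.25), miR-93 (1.08) and miR-18a (1.62, well above background on 1 of 3 Control arrays), with a list median of 1.20 (camera adjusted p = 0.00527; adjusted p = 0.26 with an estimated correlation). In the deposited table miR-20b (0.42, adjusted p = 0.145), miR-93 (0.36, 0.279) and miR-18a (3.40, 0.14) did not pass. Of the miRNAs commonly reported higher in colorectal tumours, 8 of 9 rose and none fell, with a median of 1.40 (adjusted p = 0.00522; adjusted p = 0.26 with an estimated correlation). Among them, miR-183, miR-96 and miR-182, which share 1 cluster, rose by 1.63, 1.40 and 1.39. Of those commonly reported lower, 4 of 9 fell (miR-375, miR-378, miR-139-5p and miR-30a) and 2 rose, miR-195 (1.58) and miR-497 (1.82), both relatives of miR-16 that restrain the cell cycle. The median was -0.59 (adjusted p = 0.00239; adjusted p = 0.0779 with an estimated correlation). Of 6 intestinal epithelium-enriched miRNAs, 4 fell (miR-215, miR-375, miR-194 and miR-192) and miR-31 rose, with a median of -1.23 (adjusted p = 0.00527; adjusted p = 0.26 with an estimated correlation). Of 6 p53-responsive miRNAs, miR-34a rose while miR-215, miR-194 and miR-192 fell, with a median of -0.72 (adjusted p = 0.00643; adjusted p = 0.105 with an estimated correlation). Median scaling, quantile normalization and camera on ranks also ended the calls of the intestinal list (adjusted p = 0.0555, 0.0587 and 0.117) and the p53 list (0.0555, 0.0621 and 0.0759). Counts adjusted over the list alone were the same for these lists except for 2 rises on the intestinal list.

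Of 6 inflammation-induced miRNAs, 4 rose, miR-146b, miR-21, miR-223 and miR-132 (log2 difference 0.69, or 1.99 with the lowered floor), while the list did not pass (median 0.90, adjusted p = 0.125, or 0.000208 with fry). miR-146a differed by 0.39 (adjusted p = 0.294, turning to -0.09 with median scaling) and miR-155 by 0.07 (adjusted p = 0.943). Of 9 let-7 members, let-7e (1.38), let-7i (0.70) and miR-98 (0.62) rose and let-7f differed by 0.13. The let-7 list did not pass (median 0.05, adjusted p = 0.905), and its median turned to -0.43 with median scaling and -0.03 with the total gene signal. let-7i missed the threshold without Control array 2 (adjusted p = 0.068), Control array 3 (0.067) or AOM/DSS array 2 (0.0872), and miR-98 without Control array 3 (0.0657) or AOM/DSS array 2 (0.0636). miR-29c fell by 0.66, while miR-29b (-0.15) and miR-29a (-0.10) did not pass (list adjusted p = 0.119). miR-30c and miR-30a fell by 0.65 and 0.59, and miR-30d and miR-30b (both 0.48) rose only when adjusted over the list alone (list median -0.32, adjusted p = 0.196). Without Control array 2 or AOM/DSS array 3, miR-29c (adjusted p = 0.0514 and 0.0504), miR-30c (0.0768 and 0.0811) and miR-30a (0.0835 and 0.0995) missed the threshold, and miR-30a did so also without Control array 1 (0.0608) or AOM/DSS array 2 (0.0529). miR-30b passed without AOM/DSS array 2 (0.0386), and miR-30d without Control array 2 (0.0441) or AOM/DSS array 3 (0.0259). In the miR-15/16 family miR-195 and miR-497 rose, and miR-322 (0.52) and miR-15a (0.20) did not pass (list median 0.36, or -0.11 with median scaling; adjusted p = 0.613, or 0.0264 with fry). Of the Dlk1-Dio3 cluster miR-494 was the 1 member tested. The calls of let-7e, let-7i, miR-98, miR-132 and miR-195 ended with median scaling (adjusted p = 0.0538, 0.456, 0.592, 0.0708 and 0.0566), and those of let-7i, miR-98, miR-132, miR-195, miR-29c, miR-30a and miR-30c with the percentile over all probes (0.14, 0.145, 0.056, 0.056, 0.145, 0.218 and 0.188). Normexp ended those of miR-132 (0.1), miR-98 (0.152) and miR-30a (0.0576), quantile normalization that of miR-132 (0.12), the total gene signal those of miR-98 (0.0659) and let-7i (0.0776), and the deposited table those of miR-146b (0.0551), miR-497 (0.143), let-7e (0.14), miR-195 (0.11) and miR-98 (-0.09, 0.716). Without a filter on dim probes miR-132 (0.0749), let-7e (0.112), let-7i (0.179), miR-98 (0.0914), miR-29c (0.0701), miR-30c (0.12), miR-30a (0.115) and miR-195 (0.184) did not pass, nor within slide 1 did miR-132 (0.0734), let-7i (0.0806), miR-98 (0.103), miR-29c (0.1), miR-30c (0.151) and miR-30a (0.14), nor in a fit of only the 2 groups miR-98 (0.0686), miR-30c (0.0598) and miR-30a (0.087). With quantile normalization miR-98 was -0.06, miR-30d -0.16 and miR-322 -0.13, and with median scaling let-7f was -0.35 and miR-15a -0.27.

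Markers of other cell types gave these values beside the changes above. The epithelial list had a median of -0.44 (adjusted p = 0.00239; adjusted p = 0.26 with an estimated correlation, and 0.0587 with quantile normalization), with miR-215, miR-194 and miR-192 lower. None of the 5 miR-200 family members passed: miR-200a (-0.54), miR-200b (-0.35), miR-141 (0.43), miR-200c (0.08) and miR-429, with a median of 0.07 that turned to -0.40 with median scaling (list adjusted p = 0.259). With median scaling miR-200a (adjusted p = 0.0252) and miR-200b (0.038) passed as lower, as did miR-200b with quantile normalization (0.0309). Of the muscle markers miR-1a differed by -0.99 (adjusted p = 0.102), miR-143 by -0.53 (0.476) and miR-145, at the floor on all AOM/DSS arrays and Control array 2, by -0.42 (0.268, or -1.10 with the floor lowered 4 times). miR-133a was not among the miRNAs tested. The muscle list had a median of -0.53 (adjusted p = 0.119). Control array 2 decided this: without it the muscle median was -1.39 (adjusted p = 0.00668), and miR-143 (0.00899) and miR-1a (0.0108) passed. Mesenchymal markers did not pass (median 0.76, adjusted p = 0.817; miR-199a-3p 1.23, miR-199a-5p 0.86, miR-214 0.76 and miR-152 0.15), but the first 3 passed without Control array 3 (adjusted p = 0.00487, 0.00487 and 0.00417), with array weights (0.0319, 0.049 and 0.024) and within slide 1 (0.0197, 0.0201 and 0.0197). Of the leukocyte markers, miR-223 rose, and miR-342-3p (1.54), miR-150 (-1.06), miR-142-5p (-0.37) and miR-142-3p (-0.17) did not pass (list median -0.05, adjusted p = 0.815), although miR-150 did without AOM array 1 (0.0497). miR-451 of erythrocytes (1.00; adjusted p = 0.164, or 0.0307 without Control array 1), miR-126-3p of endothelium (1.19; 0.0643, or 0.0116 without Control array 3) and miR-7a of neurons (0.48; 0.0712, or 0.0334 without AOM array 1) did not pass. The other tested marker of the endothelium list, miR-139-5p, passed as lower, as given above. So did miR-375 (-2.16), the other tested marker of the neuron and enteroendocrine list. With median scaling miR-141 (-0.04), miR-200c (-0.40), miR-152 (-0.31) and miR-155 (-0.40) changed sign, and with quantile normalization miR-7a (-0.20) did. List median, mean and test differed in sign for let-7 (0.05, 0.29, lower), the miR-200 family (0.07, -0.06, lower) and leukocytes (-0.05, 0.34, lower).

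The arrays of both groups did not overlap for 93 of the 171 miRNAs (54.4%; chance gives 10%), including the 63 that passed. All 63 had the same sign within slide 1 and within slide 2, which follows from the lack of overlap and is no separate support. Slide 1 alone called 42, of which 37 were among the 63, and slide as a block called 63. The 6 lists that passed kept the sign of their median on each slide and passed with slide as a block. The share of rises depended on the scaling. The median difference of all tested miRNAs was 0.40, and 77.8% of calls were rises. With median scaling the median difference was 0.00243, with 25 higher and 27 lower (48.1% rises), and with quantile normalization 0.0743, with 33 higher and 31 lower (51.6%). The medians of the miR-17~miR-92a and tumour-higher lists stayed above 0, and those of the intestinal, p53, epithelial and tumour-lower lists below 0, under each of the scalings tried.

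**Figure D3:**
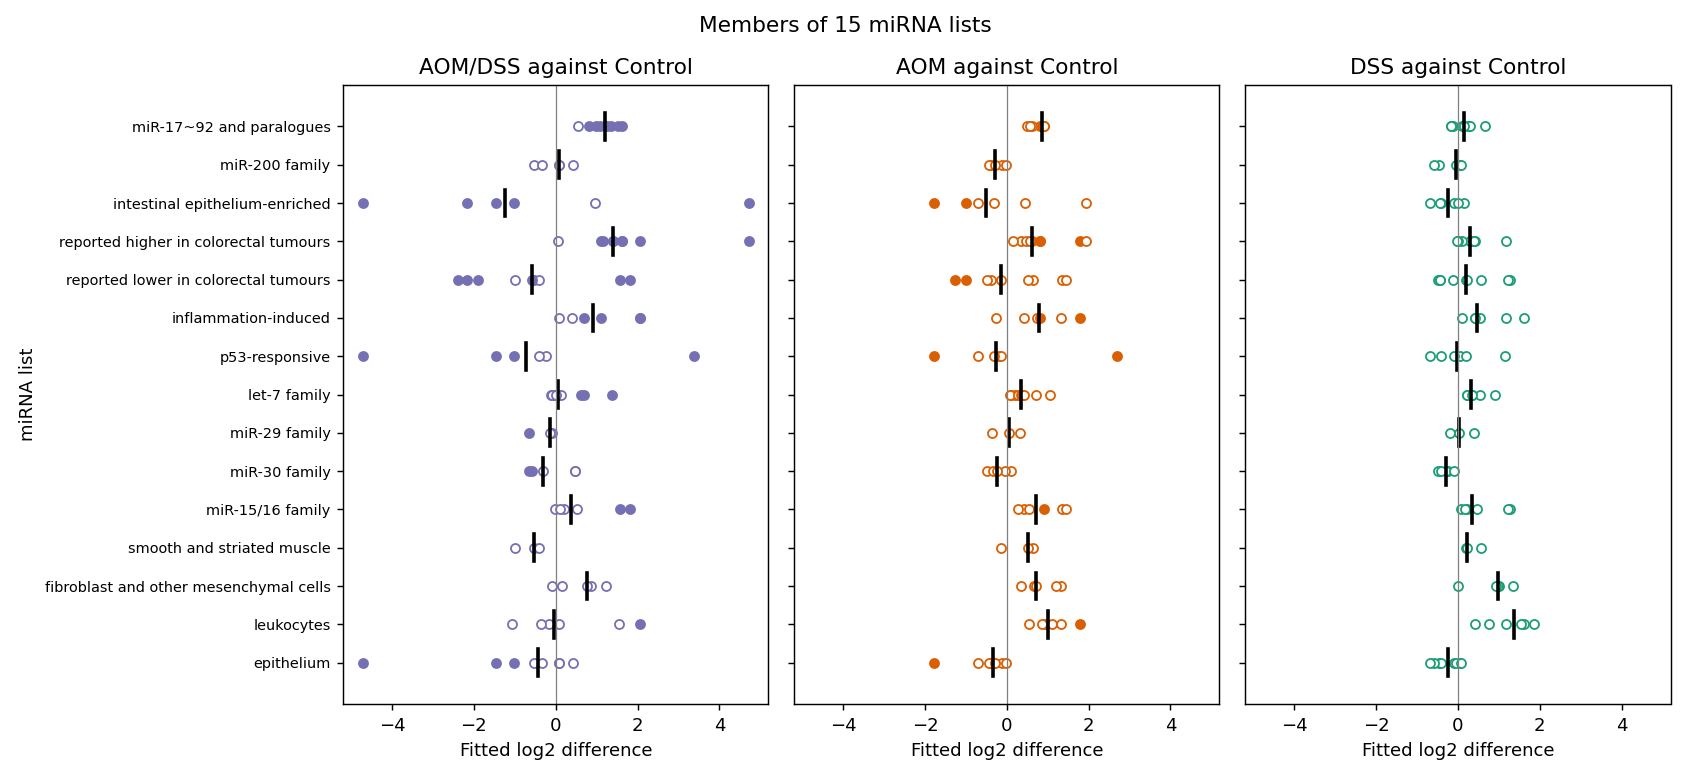
Fitted log2 differences of the members of 15 miRNA lists in AOM/DSS, AOM and DSS against Control, with 1 point per miRNA, filled where adjusted p is under 0.05, and a bar at each list's median. The miR-17~miR-92a median is 1.20 in AOM/DSS, 0.87 in AOM and 0.14 in DSS, where it turns to -0.17 with median scaling.

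AOM against Control addresses what repeated carcinogen alone left at day 100. miR-34a rose 6.44-fold, from -3.58 ± 0.45 to -0.89 ± 0.46 (n = 3 each; log2 difference 2.69, SE 0.32, adjusted p = 0.000633), and miR-223 rose 3.47-fold (1.80, SE 0.28, adjusted p = 0.00375). miR-215 was 3.41-fold lower (-1.77, SE 0.41, adjusted p = 0.0179), miR-378 2.40-fold lower, the hypoxia-induced miR-210 2.07-fold lower and miR-375 1.98-fold lower. Smaller rises were those of miR-350 (1.17), miR-205 (1.17, well above background on 2 AOM arrays and 1 Control array), miR-7a (1.00), miR-3096b-3p (0.91), miR-322 (0.91), miR-20b (0.90), miR-20a (0.89) and miR-21 (0.82, adjusted p = 0.0331). These 14 miRNAs, 10 higher and 4 lower, were all that passed, and 50 had an unadjusted p under 0.05. None of these 8 smaller rises passed with the percentile over all probes, median scaling or quantile normalization, nor did miR-223 with the percentile over all probes (adjusted p = 0.197), whereas miR-34a passed under every scaling tried. miR-210 did not pass with normexp (0.0686) and miR-375 not with the total gene signal (0.0559). In a fit of only the AOM and Control arrays, and without a filter on dim probes, no miRNA passed (miR-34a at adjusted p = 0.0663 and 0.0602). The replicate block ended the calls of miR-21 (0.0505), miR-205 (0.0562) and miR-375 (0.0665). The deposited table ended the calls of miR-223 (1.25, 0.0505), miR-215 (-1.96, 0.18), miR-350 (2.98, 0.309), miR-205 (5.69, 0.157), miR-7a (0.49, 0.246), miR-3096b-3p (0.40, 0.309), miR-322 (0.47, 0.319), miR-20b (0.31, 0.385), miR-20a (0.45, 0.309) and miR-21 (0.48, 0.309). The mean of all probes ended those of miR-350 (0.0709) and miR-205 (0.103), slide 1 alone those of miR-205 (0.208), miR-7a (0.0819), miR-3096b-3p (0.0596), miR-20b (0.0692), miR-20a (0.143), miR-21 (0.253) and miR-375 (0.0692), and the fit without AOM array 1 and Control array 2 together those of miR-350, miR-375 (both 0.0542) and miR-210 (0.0607). With the floor lowered 4 times miR-205 was at 2.06 and miR-350 at 1.53.

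miR-31 was well above background on AOM arrays 2 and 3, on neither AOM array 1 nor any Control array (log2 difference 1.94, which depends on the floor, or 3.28 with it lowered 4 times; adjusted p = 0.0567, or 3.19e-05 without AOM array 1, 0.000606 with array weights and 0.00893 with normexp). miR-135b, above the floor on AOM arrays 2 and 3 only, did not pass (0.36, adjusted p = 0.238), but did with the floor lowered 4 times (1.62, 0.0351) and with array weights (0.49, 0.035). miR-155 (1.32, 0.238), miR-142-3p (0.94, 0.374), miR-143 (0.65, 0.441), miR-145 (-0.14, turning to 0.06 with normexp and 0.53 with the lowered floor), miR-192 (-0.32) and miR-146a (-0.27) did not pass. In the miR-17~miR-92a list 2 of 9 rose, or 8 when adjusted over the list alone, with a median of 0.87 (camera adjusted p = 0.00696; adjusted p = 0.233 with an estimated correlation, and 0.0619 within slide 1). The epithelial (median -0.35, adjusted p = 0.000361) and intestinal lists (-0.51, 0.0102) lay lower, with miR-215 lower in both and miR-375 in the second (adjusted p = 0.233 for each with an estimated correlation). The miR-200 (-0.29, 0.037), miR-30 (-0.23, 0.037), p53 (-0.26, 0.037) and tumour-lower lists (-0.14, mean 0.08, 0.0404) were called lower, and the tumour-higher (0.61, 0.037) and miR-15/16 lists (0.73, 0.0428) higher. In the same order the adjusted p was 0.347, 0.286, 0.233, 0.233, 0.286 and 0.286 with an estimated correlation. The tumour-lower median turned to 0.06 with normexp. Within slide 1 the tumour-higher (0.25, adjusted p = 0.337) and tumour-lower (0.16, 0.475) lists did not pass. Quantile normalization ended the calls of the miR-200 (0.0867), tumour-higher (0.125), tumour-lower (0.145) and p53 lists (0.124), and median scaling those of the tumour-lower (0.165), p53 and miR-15/16 lists (both 0.0972). The percentile over all probes ended those of the tumour-lower (0.0615), p53 (0.0611) and miR-15/16 lists (0.0974), the total gene signal the same 3 (0.0656 each), and normexp those of the tumour-lower (0.0788) and miR-15/16 lists (0.066). With fry, a test of the list by itself, the epithelial, intestinal (both 0.19), miR-200 (0.447), miR-30 (0.226), p53 (0.439) and tumour-lower (0.354) lists did not pass, and with camera on ranks the intestinal, p53 (both 0.0688) and tumour-lower (0.158) lists did not. Leukocyte (median 1.02, adjusted p = 0.184), mesenchymal (0.72, 0.177), muscle (0.52, mean 0.35, test lower, 0.741), inflammation (0.78, 0.144), let-7 (0.36, turning to -0.03 with median scaling; 0.287) and miR-29 (0.06, turning to -0.33 with median scaling; 0.313) lists did not pass. The mesenchymal list passed without Control array 3 (0.0128) and the leukocyte list without AOM array 3 (0.0251), both with slide 1 alone (0.0255 and 0.0347), and the inflammation list with fry (0.00312).

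Single arrays decided much of this comparison. Without AOM array 1, 25 miRNAs passed, and the intestinal (adjusted p = 0.25), miR-200 (0.326), p53 (0.152), miR-30 (0.13), tumour-lower (0.0824) and miR-15/16 (0.302) lists did not. Without Control array 3, 25 passed and the tumour-higher (0.107), p53 (0.0546) and tumour-lower (0.402) lists did not, without Control array 2 the miR-200 (0.145) and miR-15/16 (0.0813) lists did not, without AOM array 2 the tumour-higher (0.0755) and miR-15/16 (0.0527) lists did not, and without AOM array 3 the tumour-higher (0.129) and tumour-lower (0.0611) lists did not. Without AOM array 1 and Control array 2 together the epithelial median was -0.01 (0.212), the intestinal one -0.26 (0.385) and the miR-200 one 0.18 (0.85), and the p53 (0.222), miR-30 (0.212) and miR-15/16 (0.385) lists did not pass either. Without AOM/DSS array 1 or 3 the miR-15/16 list did not pass (0.0531 and 0.0501). Without Control array 1 or AOM array 2, 2 miRNAs passed, and without AOM array 3, 9 did. Of the 14, miR-34a and miR-223 passed whichever single array was left out. All 14 had the same sign on each slide, which had to follow because their arrays did not overlap between groups. Slide 1 alone called 19, 7 of them shared, and slide as a block called 15. Of the 9 lists that passed, 8 kept the sign of their median on slide 1 and 5 on slide 2, where the epithelial median was 0.34 and the intestinal one 0.17. The median difference of all tested miRNAs was 0.34, with 71.4% of calls higher. With the 75th percentile over all probes 1 miRNA was called higher and 4 lower (20% higher), with median scaling 2 and 9 (18.2%), with quantile normalization 3 and 9 (25.0%), and with normexp 18 and 4 (81.8%). Arrays did not overlap for 45 miRNAs (26.3%).

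DSS against Control addresses what repeated colitis alone left at day 100. No miRNA passed with limma, and 27 had an unadjusted p under 0.05. The smallest p-values were those of miR-223 (log2 difference 1.18, SE 0.28, adjusted p = 0.145), miR-350 (1.10, SE 0.27, 0.145) and miR-34a (1.16, SE 0.32, 0.209), each higher on all 3 DSS arrays than on any Control array. miR-155 differed by 1.61 (0.278), miR-142-3p by 0.75 (0.612), miR-143 by 0.57 (0.666), miR-21 by 0.41 (0.352), miR-145 by 0.20 (0.808, turning to -0.08 with the percentile over all probes), miR-146a by 0.11 (0.906, turning to -0.23 with median scaling), miR-192 by -0.09 (0.906) and miR-215 by -0.69 (0.386). miR-31 and miR-135b were well above background in neither group.

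As lists, leukocyte markers were higher (median 1.36, camera adjusted p = 0.035), as were mesenchymal markers (0.97, 0.0495) and inflammation-induced miRNAs (0.48, 0.0495), although no member passed singly. In the same order the adjusted p was 0.472, 0.472 and 0.311 with an estimated correlation. The miR-30 (-0.29, 0.00318), epithelial (-0.25, 0.00994) and intestinal lists (-0.25, 0.0308) were lower, with adjusted p = 0.311, 0.472 and 0.472 with an estimated correlation. With fry the leukocyte, mesenchymal (both 0.183), miR-30 (0.17), epithelial (0.567) and intestinal (0.463) lists did not pass. The miR-17~miR-92a list did not pass (median 0.14, adjusted p = 0.861, turning to -0.17 with median scaling). The let-7 list passed with slide as a block (0.0389), the replicate block (0.0471) and camera on ranks (0.0474), and without Control array 1 (0.0338), DSS array 3 (0.0227) or AOM/DSS array 2 (0.0465). The miR-200 list passed with normexp (0.00392), with slide 1 alone (0.00711) and without Control array 3 (0.0168), AOM array 1 (0.0464) or DSS array 3 (0.0285), and the muscle list with slide 1 alone (0.0363). Control array 2 decided 5 of these calls: without it the adjusted p was 0.281 for leukocytes, 0.213 for mesenchymal markers and 0.115 for the inflammation, epithelial and intestinal lists, whereas the miR-30 list passed (0.00333). On its own array miR-143 was -3.13 and miR-142-3p -1.95, the lowest of the Control arrays. Without Control array 1 the mesenchymal (0.158), inflammation, intestinal (both 0.0927) and epithelial (0.066) lists did not pass, and without DSS array 2 the leukocyte (0.0897), mesenchymal and inflammation (both 0.146) lists did not. Each of 9 single arrays, AOM and AOM/DSS arrays among them, ended the mesenchymal call when left out, and each of 7 the inflammation call (highest adjusted p = 0.213 and 0.146). Without Control array 3, 11 miRNAs passed, with miR-223 (adjusted p = 0.0113) and miR-34a (0.0373) among them. Without AOM array 1, 1 passed, miR-350 (0.0276). With array weights miR-223, miR-350 (both 0.0158) and miR-34a (0.0357) passed. Slide 1 alone called 4 miRNAs, and slide as a block 0. Quantile normalization (0.115) and normexp (0.0657) ended the inflammation call, and median scaling the intestinal one (0.0542). With the replicate block the mesenchymal list (0.0581), and with slide as a block the mesenchymal (0.0586) and inflammation (0.0546) lists did not pass, and of the 6 lists 3 kept the sign of their median on slide 2, where the mesenchymal median was -0.35 and the epithelial one 0.34. The arrays did not overlap for 45 miRNAs (26.3%).

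AOM/DSS against AOM compares neoplasms with tissue given carcinogen alone, at another dose and schedule. miR-215 was 7.73-fold lower in the neoplasms, at -3.58 ± 0.91 against -0.63 ± 0.34 (n = 3 each; log2 difference -2.95, SE 0.41, adjusted p = 0.00249). miR-31 was higher (log2 difference 2.78, SE 0.61, adjusted p = 0.0167), with miR-31* at 1.95, miR-205 at 1.74, miR-1897-5p at 1.72 and miR-483 at least 3.50-fold higher. miR-139-5p was at least 2.84-fold lower, and miR-375, miR-378 and miR-365 fell by 1.17, 1.12 and 0.83. miR-31, miR-31* and miR-205 were well above background on 2 of the 3 AOM arrays and miR-1897-5p on 1. The differences of miR-31, miR-31* and miR-1897-5p depend on the floor, whereas that of miR-205 was little changed by lowering it. With the floor lowered 4 times miR-31 (3.44, adjusted p = 0.0658) and miR-31* (2.62, 0.0704) did not pass. Nor did miR-31 (5.10, 0.223), miR-31* (3.93, 0.266), miR-205 (1.79, 0.582) and miR-1897-5p (2.06, 0.536) in the deposited table, or miR-139-5p with the mean of all probes (-0.65, 0.0831). In all, 17 miRNAs passed, 12 higher and 5 lower.

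Of the lists, tumour-higher miRNAs were higher (2 of 9 rose, median 0.80, camera adjusted p = 0.0168) and tumour-lower ones lower (3 of 9 fell, median -1.12, adjusted p = 0.0134), neither with an estimated correlation (adjusted p = 0.498 and 0.121) nor with quantile normalization (0.0792 and 0.0516). The first did not pass without AOM/DSS array 1 (0.0576). Lists that did not pass here did so elsewhere: the intestinal list without Control array 3 (0.0446) or AOM array 1 (0.0491) and with the percentile over all probes (0.0223) or total gene signal (0.0458), the p53 list without the same arrays (0.0428 and 0.0416) and with normexp (0.0192), the percentile over all probes (0.0223), total gene signal (0.027) or fry (0.0118), the muscle list without Control array 2 (0.0405) or 3 (0.0428) and with the same 3 scalings (0.0167, 0.0223 and 0.0285), the epithelial list without AOM array 1 (0.0416), and the leukocyte list with the percentile over all probes (0.0223). Without AOM/DSS array 2, 3 miRNAs passed, and miR-31 (0.0693), miR-31* (0.0734), miR-483 (0.0657), miR-1897-5p, miR-139-5p and miR-378 (0.0648 each) were not among them. Without AOM array 2, 9 passed, and miR-483 (0.0605) did not. miR-365 missed the threshold without any 1 of 7 arrays, with adjusted p from 0.0548 to 0.0825, with the floor lowered 4 times (0.056) and with the replicate block (0.0644). Normexp ended the calls of miR-139-5p (0.104), miR-1897-5p (0.13), miR-483 (0.125), miR-365 (0.291), miR-378 (0.0622) and miR-375 (0.0504), and the total gene signal those of miR-31 (0.108), miR-31*, miR-205, miR-365 (0.121 each), miR-1897-5p (0.152) and miR-375 (0.0521). The percentile over all probes ended those of miR-375 (0.0876), miR-378 (0.105) and miR-365 (0.373). In a fit of only the 2 groups miR-31 (0.147) did not pass, and 3 miRNAs did. Without a filter on dim probes none did. All 17 had the same sign on each slide, which had to follow because their arrays did not overlap between groups. Slide as a block called 15, and slide 1 alone called 2. Both list medians kept their sign on each slide. Of the calls 70.6% were higher, against 90.5% with the percentile over all probes (19 higher, 2 lower), 47.1% with quantile normalization (8 and 9), 61.5% with median scaling (8 and 5) and 50% with the total gene signal (4 and 4). Arrays did not overlap for 53 miRNAs (31.0%).

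AOM/DSS against DSS compares neoplasms with tissue given colitis alone. miR-215 was 16.3-fold lower (log2 difference -4.03, SE 0.41, adjusted p = 0.000113) and the lymphocyte miRNA miR-150 lower (-2.93, SE 0.83, adjusted p = 0.0204, or -3.28 with the lowered floor; well above background on 1 of 3 AOM/DSS arrays). miR-378 and miR-375 fell by 1.94 and 1.72, and miR-139-5p was at least 3.45-fold lower. miR-31 was at least 26.4-fold higher, miR-31* at least 9.78-fold, miR-205 by a log2 difference of 2.79 (3.26 with the floor lowered 4 times), miR-34a 4.66-fold (2.22, SE 0.32, adjusted p = 0.000666) and miR-1897-5p at least 3.74-fold. In all, 50 passed, 39 higher and 11 lower.

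In this comparison 7 of 9 miR-17~miR-92a members rose (median 1.01, camera adjusted p = 0.00514) and 8 of 9 tumour-higher miRNAs rose (1.15, 0.00558), while 3 of 9 tumour-lower (-1.10, 0.00514), 4 of 6 intestinal (-0.98, 0.0436), 3 of 6 p53-responsive (-0.77, 0.0321) and 3 of 8 epithelial miRNAs (-0.21, 0.0436) fell. In the same order the adjusted p was 0.306, 0.306, 0.096, 0.43, 0.196 and 0.535 with an estimated correlation. miR-31 rose on the intestinal list and miR-34a on the p53 list. The epithelial median turned to 0.01 with the percentile over all probes and was 0.01 on slide 1. Quantile normalization ended the epithelial (0.317), intestinal (0.147) and p53 (0.109) calls, as did median scaling (0.0565, 0.0762 and 0.0565) and camera on ranks (0.106, 0.142 and 0.0743). Normexp ended the epithelial (0.114) and intestinal (0.0982) calls and that of miR-1897-5p (0.074), the total gene signal the intestinal call (0.0559), fry the epithelial call (0.0963) and the deposited table that of miR-205 (0.102). The epithelial call ended without AOM array 1 (adjusted p = 0.107), 2 (0.0531) or 3 (0.0601), DSS array 3 (0.0967) or AOM/DSS array 3 (0.0808). The intestinal call ended without AOM array 1 (0.107), 2 (0.0531) or 3 (0.065) or DSS array 3 (0.058), and the p53 call without AOM array 1 (0.0598). Within slide 1 the intestinal (0.0707) and epithelial (0.143) calls ended, and without AOM array 1 and Control array 2 together the intestinal (0.119), epithelial (0.104) and p53 (0.0697) calls did. The muscle list passed without Control array 2 (0.0349) or 3 (0.0326), within slide 1 (0.0173) and with normexp (0.0442), the percentile over all probes (0.0482) and the total gene signal (0.044), the leukocyte list with the percentile over all probes (0.041), and the inflammation (0.0132) and miR-29 (0.0454) lists with fry. miR-150 missed the threshold without DSS array 1 (0.0572), DSS array 2 (0.0624) or AOM/DSS array 2 (0.069), within slide 1 (0.0512), with the mean of all probes (0.0536) and, as did miR-1897-5p (0.0588), without a filter on dim probes (0.343). Without DSS array 1, 30 miRNAs passed, and without AOM/DSS array 2, 32 did. All 50 had the same sign on each slide, which had to follow for the 49 whose arrays did not overlap between groups. Slide as a block called 48, and slide 1 alone 20, all among the 50. Of the calls 78.0% were higher, against 52.0% with quantile normalization (26 higher, 24 lower) and 64.5% with normexp (20 and 11). Arrays did not overlap for 86 miRNAs (50.3%).

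AOM against DSS compares the single treatments. No miRNA passed with limma, and 15 had an unadjusted p under 0.05. The smallest p-values were those of miR-34a (log2 difference 1.52, SE 0.32, adjusted p = 0.101), miR-210 (-1.01, SE 0.24, 0.126) and miR-20b (0.64, SE 0.18, 0.148), with no overlap between the arrays of the 2 groups. The miR-17~miR-92a list was higher in AOM (median 0.64, camera adjusted p = 2.82e-05, or 0.248 with an estimated correlation). Its median was 0.60 on slide 1 and 0.74 on slide 2, and 4 of its 9 members rose when adjusted over the list alone. Other lists passed only in alternatives. The tumour-higher (median 0.41) and epithelial (-0.20) lists did so with slide as a block (0.0444 each) and the replicate block (0.0418 each). Slide 1 alone called the epithelial (0.009), tumour-lower (0.0175), p53 (0.019) and intestinal (0.0444) lists lower. The tumour-higher list also passed without Control array 3 (0.0396), AOM array 1 (0.00112) or DSS array 3 (0.0238), with normexp (0.0234), the percentile over all probes (0.0302) and the total gene signal (0.0392). The epithelial list did so without Control array 3 (0.0396), AOM array 2 (0.00545) or 3 (0.00198), DSS array 1 (0.0165) or AOM/DSS array 1 (0.0485), with the percentile over all probes (0.0442) and the total gene signal (0.044), and the tumour-lower list without AOM array 2 (0.0275) or DSS array 3 (0.0238). AOM array 1 correlated more with DSS arrays 1, 2 and 3 (Pearson's r 0.984, 0.976 and 0.969) than with AOM arrays 2 and 3 (0.927 and 0.915). Without AOM array 1, 18 miRNAs passed, with miR-34a (adjusted p = 0.00924), miR-20b and miR-210 (both 0.0466) among them. These 3 passed with array weights (0.00107, 0.00561 and 0.00625), and miR-34a with normexp (0.0372). Slide as a block and slide 1 alone called 0 miRNAs.

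The departure from additivity asks whether neoplasms differ from the sum of the single treatments on the log2 scale. No miRNA passed with limma, and 38 had an unadjusted p under 0.05. miR-690 (1.34, SE 0.27, adjusted p = 0.0727), miR-350 (-1.61, SE 0.38, 0.115) and miR-215 (-2.26, SE 0.58, 0.132) had the smallest p-values, and no list passed. Leaving out 1 array gave list calls: leukocytes without Control array 1 (0.0374), Control array 3 (0.0136), AOM array 3 (0.0112) or AOM/DSS array 3 (0.0493), mesenchymal (0.00551), tumour-lower (0.0112), muscle (0.0136) and miR-15/16 (0.0487) lists without Control array 3, and let-7 without AOM/DSS array 2 (0.0388). Slide 1 alone called 7 lists: leukocytes (0.00773), mesenchymal (0.013), muscle, miR-200, tumour-lower (0.0159 each), miR-15/16 (0.028) and tumour-higher (0.0476). The leukocyte list, with a median of -1.61 (adjusted p = 0.0786), passed in 10 of 24 alternatives, among them the percentile over all probes (0.000441), median scaling (0.00764), the total gene signal (0.0269), normexp (0.0341) and camera on ranks (0.045). The tumour-lower list passed with the percentile over all probes (0.0143), the total gene signal (0.0269), fry (0.0407) and normexp (0.047), the p53 list with fry (0.0407), and the miR-200, miR-30, muscle and mesenchymal lists with normexp (0.0359 each). Without AOM array 1, 4 miRNAs passed, with miR-690 (adjusted p = 0.0402) and miR-350 (0.0457) among them. Without AOM array 3, 6 passed (miR-690 0.0343, miR-350 0.0304), without AOM/DSS array 1, 3 did (miR-215 0.00886), and without Control array 3, 1 did. miR-690 also passed with median scaling (0.033) and in the deposited table (0.0306). Slide as a block and slide 1 alone called 0 miRNAs.

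The differences from Control in AOM and in AOM/DSS went together. Of the 14 miRNAs that passed in AOM, 10 passed with the same direction in AOM/DSS: miR-34a, miR-223, miR-205, miR-20a, miR-20b, miR-21 and miR-3096b-3p higher, and miR-215, miR-375 and miR-378 lower. Independent lists of these sizes would share 2.87 higher and 0.328 lower. Unchanged groups simulated against the same Control arrays shared 0.01. Such groups give few calls of any kind, so this low count was fixed in advance and is no yardstick for the 10. The 3 Control arrays were too few to split, so part of the excess over independent lists may come from their sharing. Across miRNAs, which are not independent replicates, Pearson's r was 0.761 (0.504 in simulated unchanged groups), and the covariance was 0.470 against 0.0668 simulated, a difference of 0.403. For AOM and DSS r was 0.709 (simulated 0.499) and the covariance 0.203 (0.0656), and for AOM/DSS and DSS r was 0.366 (0.497) and the covariance 0.184 (0.0659).

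**Figure D4:**
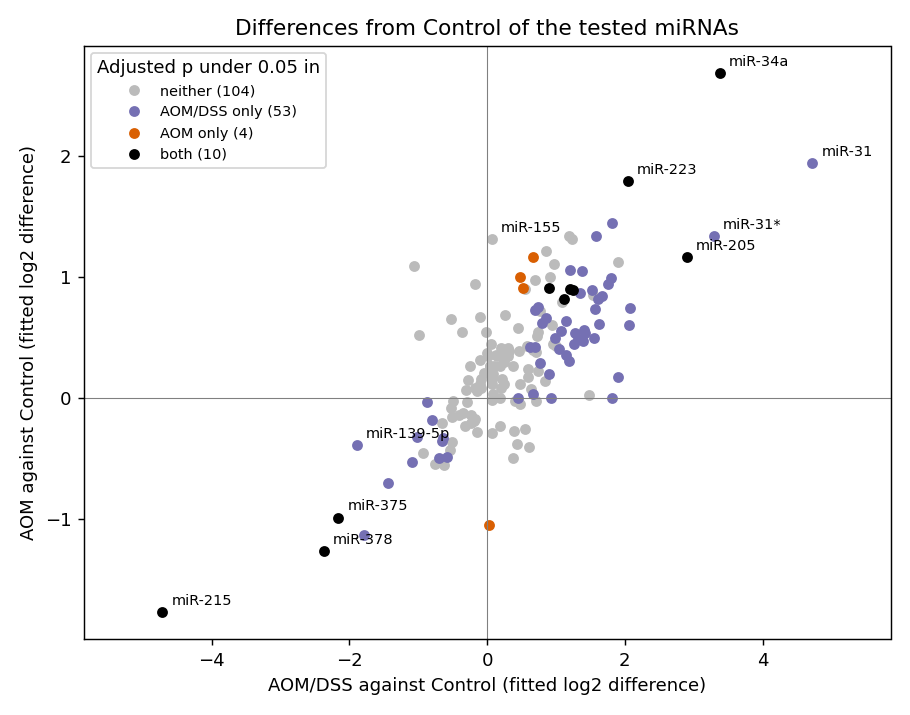
Fitted log2 differences of 171 miRNAs in AOM/DSS against Control (horizontal) and AOM against Control (vertical), with 1 point per miRNA, coloured by where adjusted p was under 0.05. The 10 miRNAs past the threshold in both lie in the lower left and upper right, and 53 passed in AOM/DSS alone and 4 in AOM alone.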

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

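All tests of explanations here were chosen after the result was seen, apart from the counts of other splits of the arrays.

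Probes for viral miRNAs were not part of the comparisons as a group, apart from 1 tested name, and some exceeded the Control arrays, where none of 57 viral names was well above background. Of these names 1 was well above background on any AOM array, 1 on any DSS array and 4 on any AOM/DSS array. mcmv-miR-M23-1-5p was so on 3 AOM/DSS arrays and 1 AOM array, and each of the others on 1 array of a group. No explanation was tested for these signals as a group. Background and overall signal are examined below for a set of miRNAs that includes mcmv-miR-M23-1-5p. Viral infection and cross-hybridisation of mouse RNA both stay open.

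The 10 miRNAs that passed with the same direction in AOM and in AOM/DSS against Control, miR-34a, miR-223 and miR-215 among them, raise the question of what the 2 groups share. The covariance was 0.470, where the highest of 100 simulations with unchanged groups was 0.110. These simulations drew each miRNA independently, whereas Control array 2 and AOM array 1 stood apart on the second principal component. Deviations common to many miRNAs widen the spread of a covariance. The simulations therefore cannot exclude the shared Control arrays as the whole source. Neoplasm-like tissue making up 1 share of each AOM sample would need shares of at least 25.0%, 66.7% and 60.6% on AOM arrays 1, 2 and 3 for 9 of the 10. miRNAs well above background on no Control array needed at most 13.9%, 33.5% and 40.2%. miR-205 would need 6.72%, 16.9% and 39.98%, within these limits. The 10 were chosen for passing in AOM against Control, which favours high shares, whereas the miRNAs on no Control array were not. The gap therefore cannot decide the question, and such a share stays open. An effect of AOM that both groups carry was not separately tested, and the DSS values do not set it apart from one common to all 3 treatments: miR-223 and miR-34a differed from Control by 1.18 and 1.16 in DSS without overlap of arrays, no miRNA passed in AOM against DSS (15 with an unadjusted p under 0.05), and the covariance of AOM and DSS was 0.203 against 0.0656 simulated. Other values go the other way. The miR-17~miR-92a list, with miR-20a and miR-20b, had a median of 0.14 in DSS against Control and 0.64 in AOM against DSS. In the latter comparison it passed with camera's preset correlation but not with an estimated one (adjusted p = 0.248). miR-34a passed there without AOM array 1. Both kinds of effect stay open. Different shares of several tissue states stay open too.

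For the 63 miRNAs past the threshold in AOM/DSS against Control, the neoplasms were also collected in another way than the Control tissue. Of them, 10 miRNAs passed with the same direction in AOM against Control, 2 groups collected alike, where independent lists would share 3.19. Both comparisons use the same Control arrays, so 3.19 is not the number that unchanged groups would share. No miRNA passed in a fit of only the AOM and Control arrays. The count therefore does not decide whether collection was the whole cause for these 10. For the other 53 the way of collecting, the tumour itself and the share of cell types cannot be told apart, because the design joins collection to the group. The 14 falls, whose median was -1.05, were also set against the miR-200 family of the epithelial list. That family had a median of 0.0738 and an SD of 0.384 over its 5 members. Median scaling, which lowers all differences, gave it -0.40 and called 27 miRNAs lower. The falls were chosen for passing as lower, which favours such a gap, and miR-200 levels per epithelial cell were not measured. A lower share of epithelial cells as the whole cause of the falls therefore stays open.

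The 8 miRNAs past the threshold that were well above background in AOM/DSS and on no Control array include miR-31, miR-31*, miR-135b and miR-483, and 1 of them is the viral name mcmv-miR-M23-1-5p. A higher general background on the AOM/DSS arrays was not settled by the viral probes, 57 names with mcmv-miR-M23-1-5p among them. Their median signal differed by -0.890 (SD 1.40), while the smallest rise of the 8 was 15.6 signal units. This signal is already background-subtracted, which holds the median of mostly undetected probes near 0. The median local background was 36, 35 and 28 on the Control arrays and 35, 36 and 35 on the AOM/DSS arrays. A lower overall signal on the Control arrays as the source of the median bound of 1.48 for the 8 is argued against by the scaling signal. It differed by 0.0812 on the log2 scale (SD 0.467). Only the median was compared, and miR-149 among the 8 differed by 0.67, so the test does not cover each member. For the 7 mouse miRNAs expression that appears in the neoplasms is a candidate explanation. Cross-hybridisation of single probes stays open for all 8 because probe sequences were not analysed here.

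With 3 arrays against 3, the 10 splits are too few for a share under 0.05. For AOM/DSS against Control the real split gave 63 miRNAs and the highest other 0, with 1 split as large, the real one. For AOM against Control the values were 14 and 0 (1 split), for AOM/DSS against AOM 17 and 6 (1 split), and for AOM/DSS against DSS 50 and 0 (1 split). For DSS against Control and AOM against DSS every one of the 10 splits gave 0. For the departure from additivity the real value was 0 and the highest other 2. A count of 0 is reached by any split, so the 100 of 100 drawn splits that reached it were fixed in advance and say nothing about chance.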

How the results depend on the processing

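The fits on slide 1 alone and without AOM array 1 and Control array 2 together were chosen after seeing the data, and all others were planned. Among the alternative counts of miRNAs past the threshold, 156 lay within 1.5 times the reported count and 53 did not. Of the values for named miRNAs, 3259 stayed on their side of the threshold, of which 69, past it in neither fit, had the opposite sign. A call was lost by 287 and gained by 65, and 2 values of a called miRNA changed sign. Those 2 were miR-98 in AOM/DSS against Control, at -0.0558 with quantile normalization and -0.0910 in the deposited table. For lists, 2259 stayed on their side, of which 92, called in neither fit, had the opposite direction, 156 lost the call and the rest gained one. Signal near background limits the faint miRNAs, many of which lie at the floor in some group. Where fewer miRNAs or arrays entered a fit, that is part of its construction; otherwise the cause was not tested.

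With the 75th percentile over all probes AOM against Control had 5 miRNAs and the departure from additivity 1. Array weights gave 50 for AOM against Control, 6 for DSS against Control, 29 for AOM/DSS against AOM and 35 for AOM against DSS. The deposited table gave 8 for AOM against Control, 2 for DSS against Control, 1 for AOM against DSS and 6 for the departure. Testing only miRNAs detected on all 12 arrays gave 37 for AOM/DSS against Control, 23 for AOM against Control, 5 for AOM/DSS against AOM, 27 for AOM/DSS against DSS, 1 for AOM against DSS and 1 for the departure. A floor lowered 4 times gave 1 for DSS against Control and 11 for AOM/DSS against AOM. The median over probes detected on all arrays gave 1 for the departure. Without a filter on dim probes, with 1080 names tested, there were 28 for AOM/DSS against Control, 0 for AOM against Control, 0 for AOM/DSS against AOM and 19 for AOM/DSS against DSS. Normexp gave 22 for AOM against Control, 4 for AOM/DSS against AOM, 31 for AOM/DSS against DSS and 1 for AOM against DSS. Fits of only the groups compared, not possible for the departure, gave 0 for AOM against Control and 3 for AOM/DSS against AOM. Total gene signal gave 8 for AOM/DSS against AOM and 1 for the departure. Slide 1 alone gave 4 for DSS against Control, 2 for AOM/DSS against AOM and 20 for AOM/DSS against DSS. Without AOM array 1 and Control array 2 together there were 22 for AOM against Control, 21 for AOM against DSS and 6 for the departure, with AOM/DSS against Control at 73.

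Leaving out each array in turn gave 55 to 74 miRNAs for AOM/DSS against Control, 2 to 25 for AOM against Control, 0 to 11 for DSS against Control, 3 to 22 for AOM/DSS against AOM, 30 to 61 for AOM/DSS against DSS, 0 to 18 for AOM against DSS and 0 to 6 for the departure from additivity. With the replicate block the counts were 59, 11, 0, 13, 46, 0 and 0 in the same order. Replicate numbers did not pair the arrays: of 18 same-number pairs 7 had a correlation above 0.1, from -0.512 to 0.515, and 3 arrays correlated best with their own number.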

Other observations

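The tests here were chosen after the result was seen.

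miRNAs encoded next to each other differed alike between neoplasms and Control. Of 171 tested names 120 matched a gene, and 109 hairpins had a single locus, giving 16 pairs within 10000 bases. Examples are miR-182, miR-183 and miR-96 (log2 differences 1.39, 1.63 and 1.40), miR-195 and miR-497 (1.58 and 1.82), let-7e and miR-99b (1.38 and 1.27), and miR-25 and miR-93 (0.80 and 1.08). All 16 pairs had the same sign, against 9.98 on average in random pairings. The pairs are not separate observations. miR-17*, miR-18a, miR-19a and miR-20a were all paired with each other, as were miR-182, miR-183 and miR-96. The mean absolute difference within pairs was 0.264, against 1.16 on average in 10000 random assignments (permutation p = 1e-04, the smallest they can give). Shared transcription of a cluster may account for this, and similar probe sequences within some clusters stay open.

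Both arms of 10 hairpins were tested in AOM/DSS against Control, and all 10 pairs had the same sign. miR-192 and miR-192* differed by -1.02 and -1.09, miR-30a and miR-30a* by -0.59 and -0.70, and miR-149 and miR-149* by 0.67 and 1.19. miR-149 was well above background on no Control array, so its 0.67 is a lower bound. miR-378 differed by -2.38 (adjusted p = 5.4e-05) but miR-378* by -0.19 (adjusted p = 0.358). The departure from additivity of miR-378* was 0.192, the exact reverse, as happens when every treated group lies at the floor. The floor would then cap its fall, so these values cannot show that this arm fell less. The difference between the arms was not tested.

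AOM array 1 was unlike AOM arrays 2 and 3 (Pearson's r 0.927 and 0.915), which were alike (0.983). It correlated more with DSS arrays 1, 2 and 3 (0.984, 0.976 and 0.969) than with either of them. The same held for Control arrays 1 and 3 (0.952 and 0.942) but not for Control array 2 (0.888). miR-31 was -4.71, the floor, on AOM array 1, -2.17 on array 2 and -1.43 on array 3. The leukocyte marker miR-342-3p was -0.98 on AOM array 1, -3.75 on array 2 and -2.58 on array 3, and miR-155 was -0.34, -2.65 and -3.44. These examples were chosen after their values were seen. The labels give no further detail on these samples, and no explanation was tested.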
